A study of Homo sapiens with 9 samples.

How the data were processed

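ATAC-seq, which maps open chromatin by transposase insertion, was read from 9 peak lists of 22Rv1 cells, a human prostate carcinoma line, edited to carry the C1111S form of the splicing factor SF3B1. Per the labels, 3 libraries came from cells given DMSO (0.1%, the vehicle), 3 from cells given WX-02-23 and 3 from cells given WX-02-43, both at 20 µM, and every treatment lasted 3 h. Libraries were made with a commercial ATAC-seq kit, per the labels' protocols. Reads were aligned with Bowtie2 to hg19 and peaks were called with MACS2, per the submitters' processing notes. The tool versions, the MACS2 settings, any shift of read ends for the transposase, the removal of duplicate reads and the use of a control library are not given in the sources used here. Each file was a list called on one library, so replicates were not pooled.

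The authors' deposited lists give for each peak an interval, a summit, a score, a fold enrichment over the local background (a ratio), and a −log10 p and a −log10 q at the summit. The lowest −log10 q per list lay between 2 and 2.17, and the shortest peak in every list was 150 bp. The deposited score repeats the −log10 q on a larger scale and was not used further. Scores, folds and −log10 values are the authors' own per-peak values, set within one library, and served mainly to describe, rank or filter peaks within a list. The median fold per list was also compared between groups by the exact test used for peak numbers. Folds of named regions are set side by side between groups without a test. Read totals were not analysed here. Fold and p were instead solved together for the summit pileup and the background under the Poisson formula of MACS2. A whole-number pileup matched the deposited −log10 p within 0.002 for 98.67% or more of the summits of every list, against at most 1.31% when the p-values of a list were shuffled among its peaks. The commonest background, in fragments, then described the relative depth of each library and entered no test of regions. Fragments here means the units that MACS2 stacked, which may be reads or read pairs, since its settings are not given. No more than 0.12% of intervals were identical between any pair of lists, so no list was a copy of another. This does not tell whether any lists came from the same library.

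Intervals on chromosomes 1 to 22 and X from all 9 lists were merged where they shared at least 1 bp, and a library held a merged region if any of its peaks overlapped it. Gained regions were held by all libraries of the first group and by none of the second, and lost regions were the opposite. Such counts were set beside those of every other split of the same libraries. There are 10 splits of 6 libraries into 3 and 3, which cannot give a share under 0.1, and 84 splits of 9 libraries into 3 and 6, tested one-sided for larger counts. List similarity was the Jaccard index of covered bases, tested one-sided over the 280 partitions into 3 groups of 3 and over the 84 splits. Peak numbers were tested over the same 280 partitions, and pairs of groups by an exact two-sided permutation test of the means with Benjamini-Hochberg adjustment over the 3 pairs. The 90% interval given for a difference of means holds the shifts that this exact test does not exclude. The labels do not say that replicates were separate cultures, so these p-values measure only the spread between these samples, which may be technical.

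Regions are named by a rule: the 12 gained and 12 lost regions of WX-02-23 against the other 6 libraries, and the first 5 of each for every pair of groups, ranked by the worst percentile of −log10 q over the lists that hold the region. The tests of the region counts, list similarity and peak number, the naming rule and the following other settings were fixed before the data were examined. They were a threshold of −log10 q of at least 5 on all peaks or on the present side alone, at least 50% of a region covered, lists shortened to the length of the shortest (81962 peaks, equal-length lists) or to 50000 peaks by −log10 p, windows of 100 bp either side of each summit, leaving out each library, and a replicate block. Coordinates are hg19 as the deposited lists give them, written from 1. A genome and annotation of that build were not used here, so the 19 motifs and 9 gene lists planned were not analysed and regions are given without gene names.

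The region counts were tested on simulated data. Presence tables for 128994 regions were drawn from the observed frequencies, with 200 regions per direction changed for WX-02-23 against the other 6 libraries, in 5 draws. The count recovered 76.2% of gained and 68.9% of lost regions, where the simulated probabilities of 0.95 and 0.02 for holding a peak implied 75.9% and 69.2%. The match checks the counting alone, since the probabilities fix it. Tables simulated with no change gave at most 124 gained and 51 lost regions. Each library was drawn independently there, so any structure between lists was left out. Other splits of the real libraries reached 381 gained and 431 lost regions, so the simulated counts understate what a grouping can give. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.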

Results

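Chromatin accessibility was profiled in 22Rv1 prostate carcinoma cells whose SF3B1, a core subunit of the splicing machinery, carries the C1111S change. The series concerns covalent small molecules that redirect FOXA1, a pioneer transcription factor that opens chromatin in prostate epithelium. The compounds WX-02-23 and WX-02-43, called stereoprobes in the labels, were compared with DMSO and with each other at one dose (20 µM) and one time (3 h), with 3 libraries per group.

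The 9 lists held between 81962 and 105132 peaks on chromosomes 1 to 22 and X. Peak number did not differ detectably between treatments. It averaged 91065 ± 9568 in DMSO, 96034 ± 7921 in WX-02-23 and 91486 ± 8092 in WX-02-43 (SD, n = 3 each; exact permutation p = 0.754 over 280 partitions). WX-02-23 exceeded WX-02-43 by 4548 peaks with a 90% interval from -6959 to 22814 (exact p = 0.6, adjusted p = 0.9), and DMSO by 4968 peaks with an interval from -10365 to 23170 (exact p = 0.5, adjusted p = 0.9). WX-02-43 exceeded DMSO by 421 peaks, with an interval from -18720 to 15670 (exact p = 0.9, adjusted p = 0.9). These intervals are wide, and 3 libraries against 3 cannot give a p below 0.1. Peaks covered 33.8 to 45.7 Mb per library, with median widths of 318 to 331 bp. The median width averaged 320 ± 2 bp in WX-02-43 and 328.7 ± 4.04 bp in DMSO (SD, n = 3 each; exact permutation p = 0.1, adjusted p = 0.3). The commonest background pileup ran from 1 to 1.41 fragments, and the median summit pileup from 21 to 24, so depth was of a similar order in all 9 libraries. At background level, the lowest pileup called as a peak was 6 to 8 fragments.

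**Figure D1:**
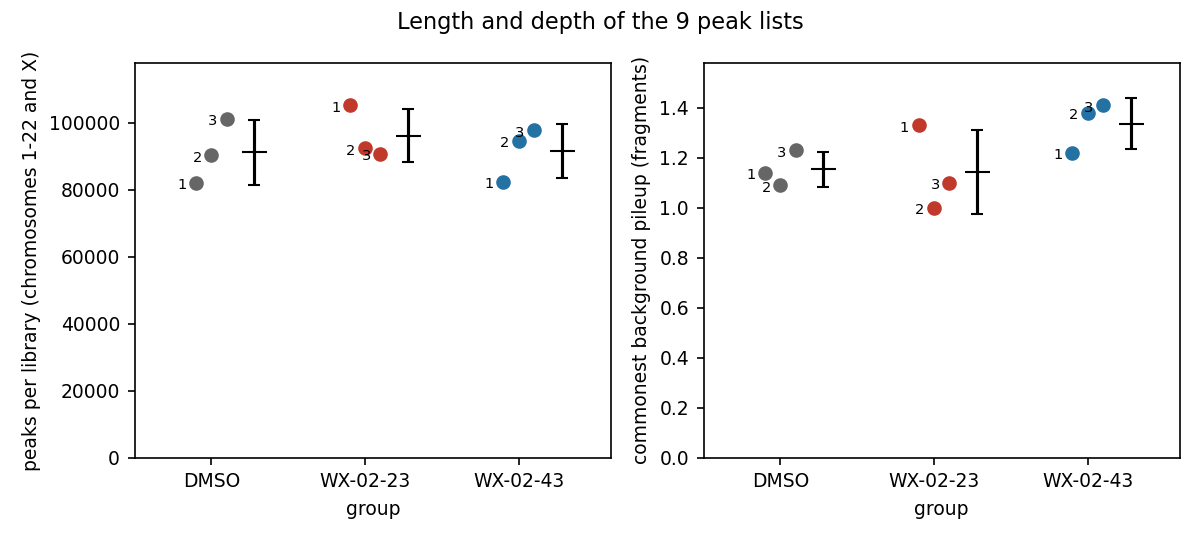
Peaks per library (left, number of peaks) and commonest background pileup (right, fragments) for DMSO, WX-02-23 and WX-02-43, with one point per library numbered by replicate and the mean with SD beside it. Peak numbers overlap between groups, with means of 91065, 96034 and 91486, and the spread within each group exceeds the differences between means.

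Merging the lists gave 128994 regions with a median width of 366 bp. All 9 libraries shared 59637 of them (46.2%), and 21250 (16.5%) were held by a single library. The shared regions were the strongest, with a median fold enrichment of 8.82 and a median width of 621 bp.

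On average, libraries given WX-02-23 resembled one another more than they resembled either other group. The Jaccard index of covered bases averaged 0.715 within WX-02-23, 0.719 within DMSO and 0.716 within WX-02-43. It was 0.692 between WX-02-23 and DMSO and 0.692 between WX-02-23 and WX-02-43, but 0.715 between WX-02-43 and DMSO. Single pairs overlapped in these lists. WX-02-23 replicate 1 reached 0.7101 with DMSO replicate 3, against 0.7053 with WX-02-23 replicate 2. Similarity within groups exceeded that between groups by 0.0169 (exact permutation p = 0.0143, 4 of 280 partitions). For WX-02-23 against the other 6 libraries, the excess was 0.0236, the highest of the 84 splits (exact permutation p = 0.0119, the smallest possible). For WX-02-43 against DMSO the excess was 0.0025, and 4 of 10 splits gave as much.

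**Figure D2:**
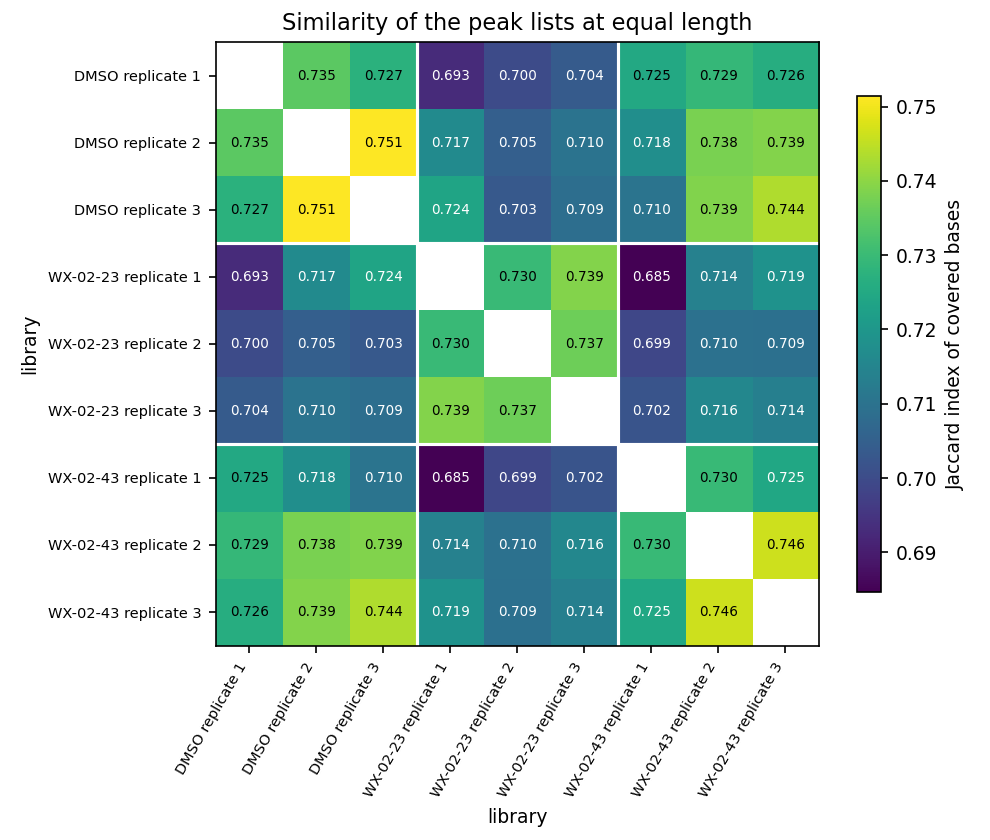
Jaccard index of covered bases (no unit) for each pair of the 9 libraries, with every list shortened to 81962 peaks; white lines part the groups. WX-02-23 libraries share less with DMSO (mean 0.707) and with WX-02-43 (mean 0.707) than with each other (mean 0.735), while WX-02-43 and DMSO average 0.730.

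WX-02-23 was next set against all 6 libraries without it, which isolates regions that set this compound apart from both the vehicle and the other stereoprobe. In all, 1161 regions were held by the 3 WX-02-23 libraries and by none of the other 6, and 469 were held by the other 6 and by no WX-02-23 library. Each count was the largest of the 84 splits (exact permutation p = 0.012 for each, the smallest possible). The highest of the other splits gave 381 gained and 431 lost regions. Gained regions made up 71.2% of these calls in the deposited lists and 57.4% in equal-length lists, where 916 were gained and 680 lost and the highest other splits gave 157 and 148. The criterion asks fewer libraries to hold a gained region than a lost one. The medians over the 84 splits were 50.5 gained and 31 lost in deposited lists, and 57.5 and 47 in equal-length lists. The excess of gained over lost regions thus depended on list length, and part of it may come from the criterion. With all 9 libraries, both directions stood above every other split in either setting. The gained count rose to 2064 without WX-02-23 replicate 2 and to 2164 without WX-02-23 replicate 3, and the lost count rose to 1033 without WX-02-23 replicate 1, since fewer libraries then had to meet the criterion. In the deposited lists the lost count no longer led without replicate 2 (612 against 1100 in another split) or without replicate 3 (597 against 1123).

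The 12 named gained regions were well above background. In the list where each ranked lowest, it stood within the first 19.9% to 41.3% of peaks. The first by rank lay on chromosome 13 from 105137888 to 105138519, with a fold enrichment of 14.9 ± 1.02 (SD, n = 3) and 33 to 45 fragments at the summit in WX-02-23, and no peak in any DMSO or WX-02-43 library. A region on chromosome 11 from 103646357 to 103646869 reached 12.8 ± 0.33 fold, and one on chromosome 1 from 227632361 to 227632954 reached 8.88 ± 0.29 fold with 40 to 53 fragments. Chromosome 13 held a pair of further named regions, from 40590949 to 40591564 (10.2 ± 0.51 fold) and from 27083812 to 27084491 (11.2 ± 1.26 fold). Chromosome 8 held 3, from 38140335 to 38140867 (9.62 ± 0.75 fold), from 84625981 to 84626426 (13.2 ± 2.48 fold) and from 29513258 to 29513870 (9.17 ± 0.7 fold). The other 4 were on chromosome 12 from 32329450 to 32329910, chromosome 3 from 80939907 to 80940495, chromosome 1 from 24329840 to 24330274 and chromosome 9 from 88223889 to 88224292, with mean folds of 9.4, 12.3, 11.3 and 10.4 in WX-02-23.

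The lost regions were likewise well above background in the libraries that held them. On chromosome 2 from 50945300 to 50945973, the 6 DMSO and WX-02-43 libraries averaged 10.3 ± 1.29 fold (SD, n = 6) with 26 to 42 fragments, and no WX-02-23 library had a peak. Regions on chromosome 9 from 81125003 to 81125502 (11 ± 0.86 fold), chromosome 3 from 64486930 to 64487621 (10.8 ± 1.3 fold) and chromosome 6 from 78363505 to 78364079 (10.8 ± 1.25 fold) showed the same layout, as did chromosome 1 from 49655622 to 49656241 (10.9 ± 1.44 fold) and chromosome 3 from 133449644 to 133450319 (10.9 ± 1.4 fold). The remaining 6 had mean folds of 6.94 to 10.4 and lay on chromosome 17 from 31158575 to 31159087, chromosome 10 from 17204872 to 17205287, chromosome 4 from 80053880 to 80054370, chromosome 2 from 284884 to 285471, chromosome 3 from 168922145 to 168922883 and chromosome 11 from 35134259 to 35134692. All 24 named regions met the same criterion in equal-length lists. That outcome was fixed in advance, since shortening adds no peak and their peaks ranked high enough to stay. The full sets were weaker than the named regions. Their median summit pileup was 13 fragments for gained and 15 for lost regions, against 33 for regions held by all 9 libraries. The median −log10 q was 7.2 and 8.4, against 21.1. Gained regions had a median fold of 5.78 and a median width of 331 bp, against 5.05 and 264 bp for other regions held by 3 libraries. Lost regions had a median fold of 6.2 and a median width of 383 bp, against 5.55 and 320 bp for other regions held by 6. A missing peak means that no call passed the authors' threshold, not that signal was absent.

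**Figure D3:**
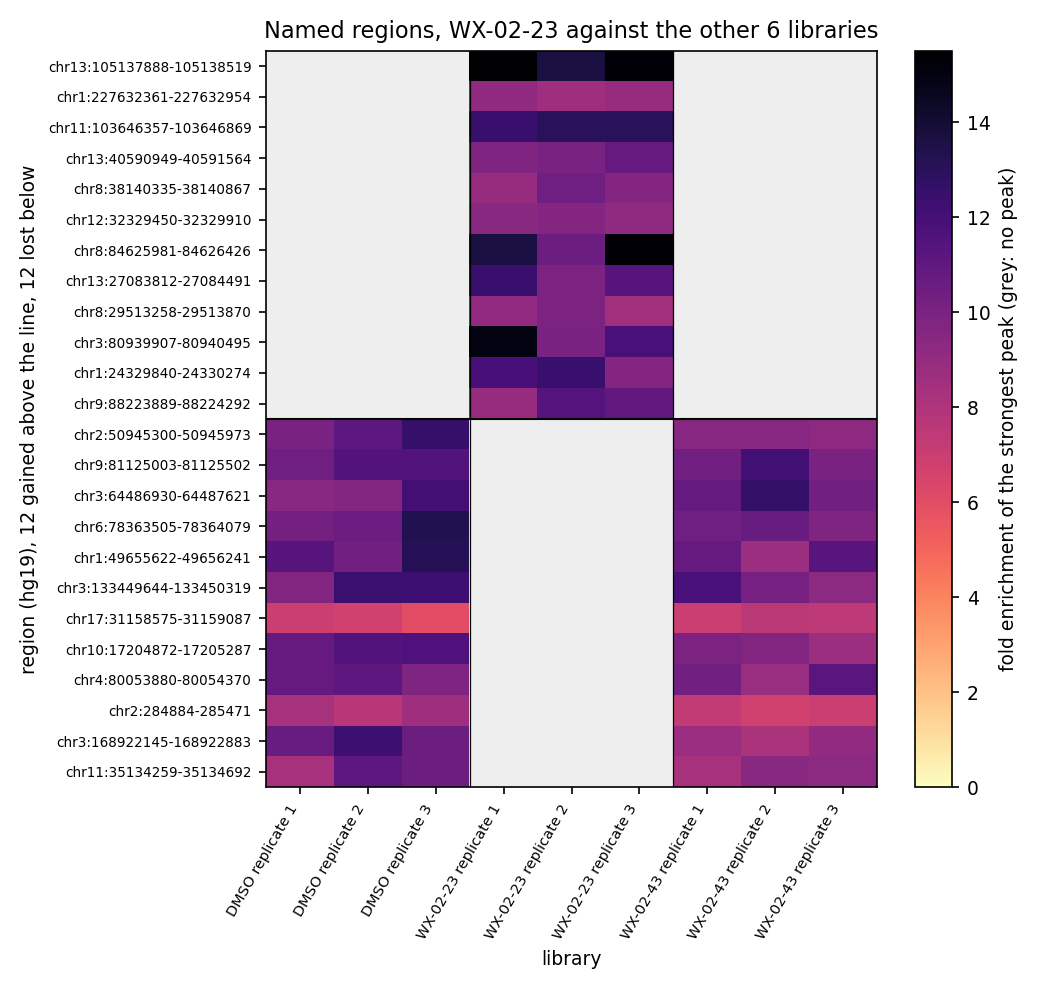
Fold enrichment of the strongest peak (colour, ratio over local background) in each of the 9 libraries at the 12 gained and 12 lost regions named for WX-02-23 against the other 6 libraries, in hg19; grey marks a library without a peak. Gained regions have peaks in the 3 WX-02-23 libraries alone and lost regions in the other 6 alone, by the criterion that selected them.

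WX-02-23 against DMSO asks what the compound changed relative to its vehicle. WX-02-23 gained 2277 regions and lost 953, and equal-length lists gave 1800 gained and 1451 lost. The gained share was 70.5% in the deposited lists and 55.4% in equal-length lists. The highest of the other 9 splits gave 1295 regions in the deposited lists and 429 in equal-length lists. Of the first 5 gained regions, those on chromosome 13 from 105137888 and on chromosome 1 from 227632361 had no peak with WX-02-43 either. On chromosome 4 from 148492238 to 148492780, WX-02-23 averaged 12.2 ± 0.75 fold (SD, n = 3) and a single WX-02-43 library held a peak, of 4.98 fold. A pair of the 5 were held by all 3 WX-02-43 libraries. On chromosome 18 from 37004115 to 37004623, fold enrichment was 14.5 ± 0.81 with WX-02-23 and 6.18 ± 1.78 with WX-02-43, with 29 to 35 and 10 to 17 fragments. On chromosome 12 from 101436853 to 101437560, it was 8.91 ± 1.05 and 4.91 ± 0.62, with 41 to 52 and 14 to 18 fragments. The first 5 lost regions were all held by the 3 WX-02-43 libraries. They comprised those above on chromosomes 2, 1, 9 and 10 and a region on chromosome 6 from 5414766 to 5415191, with 11.6 ± 1.05 fold in DMSO and 8.82 ± 0.72 in WX-02-43. All named regions were ranked on the lists of the group that had to hold them. Lower values in the group outside the comparison were therefore favoured by the choice and do not show a graded effect. With 10 splits, no share below 0.1 was possible. The gained count exceeded 1.5 times its value without DMSO replicate 3 (4136), WX-02-23 replicate 2 (3799) or WX-02-23 replicate 3 (3973), and the lost count without DMSO replicate 1 (2345), DMSO replicate 2 (1614) or WX-02-23 replicate 1 (2135).

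WX-02-43 against DMSO gave far fewer regions, 427 gained and 472 lost in the deposited lists and 468 and 529 in equal-length lists. The highest of the other 9 splits gave 1632 in the deposited lists, above both counts, and 451 in equal-length lists, just below both. The named regions were weak. The first gained, on chromosome 7 from 80599680 to 80600082, averaged 6.79 ± 0.37 fold (SD, n = 3) with 15 fragments in every WX-02-43 library, and the others, on chromosome 19 from 43588424 to 43588700, chromosome 2 from 15219769 to 15220186, chromosome 6 from 27261587 to 27261796 and chromosome 17 from 19550516 to 19551133, averaged 3.2 to 7.27 fold. The first lost, on chromosome 10 from 66305807 to 66306287, averaged 8.53 ± 0.54 fold in DMSO, and those on chromosome 3 from 14899051 to 14899334, chromosome X from 68089278 to 68089605, chromosome 4 from 115387480 to 115387776 and chromosome 1 from 10574490 to 10574765 averaged 5.83 to 7.72 fold. None of these regions was particular to WX-02-43 or DMSO. The gained regions were also held by 1 to 3 WX-02-23 libraries each, that on chromosome 17 by all 3 at 3.79 ± 0.24 fold against 3.2 ± 0.24 with WX-02-43, and the lost regions were still held by 1 to 3, that on chromosome 10 by all 3 at 8.56 ± 3.63 fold. WX-02-43 was not separated from DMSO in the deposited lists, which does not show that it acted like the vehicle. Among the 50000 strongest peaks per list, 306 regions were gained and 302 lost, and the highest of the other 9 splits gave 242. Set against the other 6 libraries over 84 splits, WX-02-43 had 91 gained and 101 lost regions in the deposited lists (exact permutation p = 0.298 and 0.167, unadjusted), 113 and 95 in equal-length lists (exact permutation p = 0.048 each) and 95 and 69 among the 50000 strongest peaks (exact permutation p = 0.024 and 0.036). In the other 4 settings p ran from 0.119 to 0.417 by the same exact test. Most of the 84 splits divide the WX-02-23 libraries, which stood apart, so a small p here does not test WX-02-43 against DMSO. In equal-length lists DMSO against the other 6 gave 157 gained and 148 lost regions, above the counts of WX-02-43. The gained count exceeded 1.5 times its value without each of 5 libraries, reaching 1806 without WX-02-43 replicate 1 and 1504 without DMSO replicate 3, with 729, 806 and 713 without DMSO replicate 2, WX-02-43 replicate 2 and WX-02-43 replicate 3. The lost count did so without each of 4, with 1837 and 1007 without DMSO replicates 1 and 2 and 1038 and 1201 without WX-02-43 replicates 2 and 3.

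WX-02-23 against WX-02-43 compared the stereoprobes at the same dose and time. WX-02-23 gained 1848 regions and lost 1040 relative to WX-02-43, and equal-length lists gave 1457 and 1374. The gained share was 64% in the deposited lists and 51.5% in equal-length lists. The highest of the other 9 splits gave 1206 in the deposited lists and 364 in equal-length lists. Of the first 5 gained regions, those on chromosome 13 from 105137888, chromosome 1 from 227632361 and chromosome 11 from 103646357 were also absent from DMSO. The region on chromosome 2 from 23631186 to 23631616, at 11.9 ± 0.66 fold (SD, n = 3) with WX-02-23, was held by 2 DMSO libraries at 6.7 ± 0.66 fold. The region on chromosome 13 from 67660335 to 67660895, at 13.2 ± 1.89 fold, was held by 1 DMSO library at 5.38 fold. The first lost region, on chromosome 6 from 125462388 to 125462859, averaged 12.1 ± 0.41 fold with WX-02-43 and 10.2 ± 1.57 in DMSO. The next 4, on chromosomes 3, 2 and 6 as above and on chromosome 8 from 110487102 to 110487489, were also held by all 3 DMSO libraries. Here too the ranking used only the group that had to hold the region, which favours lower values in DMSO. With 10 splits, no share below 0.1 was possible. The gained count exceeded 1.5 times its value without WX-02-23 replicate 2 (3428), WX-02-23 replicate 3 (3578), WX-02-43 replicate 2 (2823) or WX-02-43 replicate 3 (3152), and the lost count without WX-02-23 replicate 1 (2184) or WX-02-43 replicate 1 (2476).

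**Figure D4:**
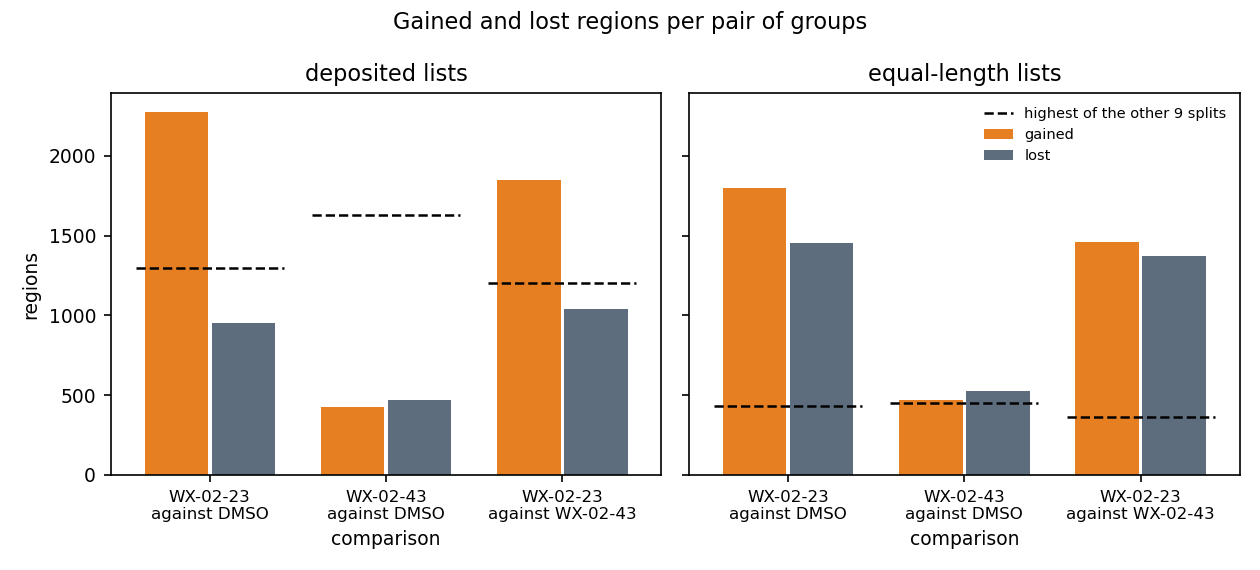
Number of gained (orange) and lost (grey) regions for each pair of groups in deposited lists (left) and equal-length lists (right); the dashed line is the highest count of the other 9 splits of the same 6 libraries. In equal-length lists WX-02-23 stands well above the line against DMSO (1800 and 1451 against 429) and against WX-02-43 (1457 and 1374 against 364), and WX-02-43 against DMSO lies just above it (468 and 529 against 451).

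**Figure D5:**
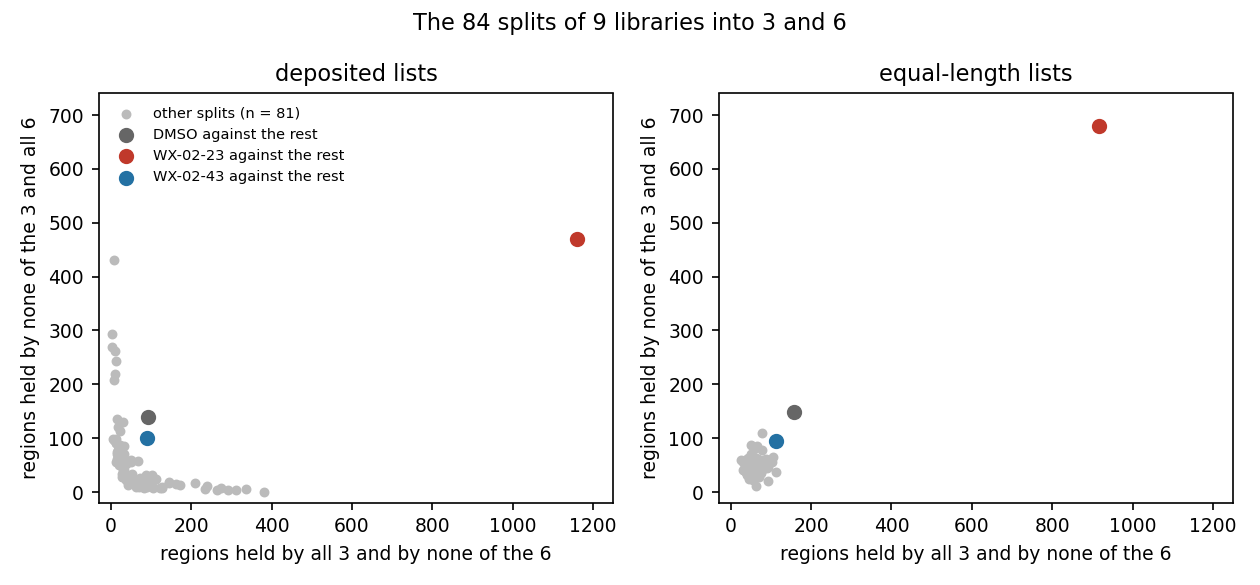
Regions held by all 3 libraries and none of the 6 (x axis, number) against regions held by none of the 3 and all 6 (y axis, number) for the 84 splits of the 9 libraries, in deposited lists (left) and equal-length lists (right). WX-02-23 lies apart from the other 83 splits in equal-length lists, at 916 and 680, and at 1161 and 469 in the deposited lists, where one other split reaches 431 lost.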

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

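The listed alternatives were planned, except the lists used for the share of opened or closed regions, chosen after the result was seen. Leaving out libraries aside, 44 of 67 alternative values kept within 1.5 times a count or on the same side of a test. Peak number and list similarity kept their side throughout: without each library, the p for peak number ran from 0.411 to 0.989 and the similarity excess from 0.0148 to 0.0196 (highest exact permutation p = 0.0286). No peaks overlap within a list, so merging them tested nothing. Motif tests, gene lists and the 20 kb distance were not run, since a genome and annotation of the build were not used here. Depth sets what can be called: at background, a peak needed 6 to 8 fragments.

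The threshold on the present side alone gave lower counts by construction, with gained regions of 1397 (WX-02-23 against DMSO), 1048 (WX-02-23 against WX-02-43), 671 (WX-02-23 against the other 6) and 148 (WX-02-43 against DMSO), and lost regions of 567 (WX-02-23 against WX-02-43), 282 (WX-02-23 against the other 6) and 249 (WX-02-43 against DMSO). The 50000 strongest peaks gave gained regions of 1173, 1008 and 662 for WX-02-23 against DMSO, WX-02-43 and the other 6, and 302 lost for WX-02-43 against DMSO, from shorter lists. Equal-length lists raised the lost count of WX-02-23 against DMSO to 1451. For WX-02-43 against DMSO, gained regions numbered 258 at the stricter threshold and 641 in summit windows; the cause was not tested. The difference in share of regions closed with WX-02-23 that was held by WX-02-43 minus DMSO was -1.44 points in equal-length and 0.95 in deposited lists (exact permutation p = 0.7 and 0.9), and the cause was not tested.

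Without each library in turn, the criterion covers fewer libraries, so counts rose. For WX-02-23 against DMSO they ran from 2525 to 4136 gained and 1178 to 2345 lost, against WX-02-43 from 2164 to 3578 and 1298 to 2476, and against the other 6 from 1203 to 2164 and 497 to 1033. For WX-02-43 against DMSO they ran from 549 to 1806 and 650 to 1837. Of 216 checks of the 54 named entries, some of which repeat a region across comparisons, 206 kept the full difference. The 10 that did not were the WX-02-43 against DMSO regions among the 50000 strongest peaks, where low ranks left out some or all of their peaks. Shortened and filtered lists are subsets of the deposited ones, and the other named peaks were strong enough to stay. Apart from those in summit windows, the outcome of these checks was thus fixed in advance.

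Over all groups, replicate numbers did not pair the libraries. In the deposited lists, correlations of deviations from group means ran from -0.059 to 0.085 for same-numbered libraries and from -0.082 to 0.05 for others. Between DMSO and WX-02-43, same-numbered pairs gave 0.018, 0.01 and 0.008 in equal-length lists, above every other pair (-0.013 to 0.003). In deposited lists these gave 0.085, 0.003 and 0.057, against -0.082 to 0.024. Same-numbered pairs with WX-02-23 ran from -0.059 to -0.008 there. A batch shared by number between DMSO and WX-02-43 was not tested and stays open. The replicate block asks for a difference in 2 of 3 pairs, a looser criterion, and gave 8594 gained and 5001 lost (WX-02-23 against DMSO), 8179 and 4928 (WX-02-23 against WX-02-43), 5430 and 2581 (WX-02-23 against the other 6) and 3972 and 4080 (WX-02-43 against DMSO). Permuting within the block gave p = 0.861 for peak number and p = 0.0278 for similarity (exact permutation, 36 arrangements).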

Other observations

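The counts over splits and the equal-length lists were planned, and the predictions for one odd library in the deposited lists and for the share of opened regions were set before those results were seen. The 4 chromosomes were picked after their shares were seen, and the prediction for them over the 84 splits was set before the split counts were seen. The tests chosen only after the result was seen were the use of the split and equal-length counts to weigh chance and list length, one odd library in equal-length lists, the lists and reference libraries for the share of opened regions, the calls shared between settings, the ranks of regions open with both compounds, and the surroundings and clustering of regions. In equal-length lists, chromosomes 16, 17, 19 and 22 together held 5.6% of the 916 gained regions against 10.7% of other regions held by 3 libraries, and 6.3% of the 680 lost regions against 11% of other regions held by 6. Chromosome 19 alone held 0.66% of gained and 0.74% of lost regions, against 2.89% and 3.25% of those matched sets. Over the splits, 23 of 84 differed from matched regions by as much as the gained set and 28 of 84 by as much as the lost set, in share on the 4 chromosomes (differences of -5.1 and -4.7 points, highest other 10.1 and 26.1 in size). The other splits held a median of only 57 gained and 47 lost regions, and such small sets differ widely by chance, so this test leaves an effect open. That limit on size was set after the counts were seen, for this test and for the surroundings.

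Some regions were open with both compounds and in no DMSO library. In equal-length lists 148 regions were held by all 6 treated libraries and by no DMSO library, a count passed only by that of WX-02-23 among the 84 splits. Most of those splits divide the WX-02-23 libraries, so this rank may partly reflect their separation. In the deposited lists the set did not stand out: it held 139 regions, and 9 of the 84 splits gave as many (exact permutation p = 0.107). As many were given by 17 splits with at least 50% of a region covered, 19 at the stricter threshold, 9 in summit windows, 13 with the threshold on the present side alone and 2 among the 50000 strongest peaks. WX-02-23 ranked the region higher than WX-02-43, by mean percentile within lists of one length, in 110 of the 148 (74.3%). In the 95 regions held by WX-02-23 and DMSO but not WX-02-43, WX-02-23 ranked higher than DMSO in 57 (60%). Both comparisons with DMSO share its libraries, so part of the 148 may come from chance absence of a peak in DMSO; the equivalent sets give 95 without WX-02-43 and 680 without WX-02-23.

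The separation of WX-02-23 from the other 6 libraries was weighed against chance, list length and single libraries. Only 1 of the 84 splits, the real one, gave as many gained (1161, highest other 381) or lost regions (469, highest other 431). This share is the smallest possible (exact permutation p = 0.012), and for the gained count it argues against a chance split without excluding one. The lost count led by a narrow margin in the deposited lists, and not without WX-02-23 replicate 2 or 3, so chance stays open for it there. The 381 came from the 3 longest lists and so points to a structure of list length. Yet with lists of one length the real counts were 5.83 and 4.59 times the highest of the other 83 splits. This argues against list length as the whole cause. Depth itself was not equalised, as background pileup ran from 1 to 1.41 fragments, so it was not tested apart from list length. With one WX-02-23 library left out, the lowest ratio of the real count to the highest other split was 3.35 in equal-length lists, but 0.53 in deposited lists, where the lost count was 597 without replicate 3 and 612 without replicate 2 against 1123 and 1100 for the pair of short lists DMSO replicate 1 and WX-02-43 replicate 1, so one odd library stays open for lost regions in the deposited lists. An effect of the compound is a hypothesis consistent with these values, and any unrecorded batch that followed the groups was not tested.

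For each pair of groups, 10 splits are too few for a share under 0.05. WX-02-23 against DMSO had 2277 gained and 953 lost regions (highest other 1295; 1 and 4 splits as large), WX-02-43 against DMSO 427 and 472 (highest other 1632; 7 and 5 splits), and WX-02-23 against WX-02-43 1848 and 1040 (highest other 1206; 1 and 2 splits). The gained share for WX-02-23 against DMSO fell by 15.1 percentage points in equal-length lists, from 70.5% to 55.4%, so list length may account for much of the surplus of gained regions. Among deposited calls of WX-02-23 against the other 6, 537 of 1161 gained and 274 of 469 lost regions were also called in equal-length lists. Equal-length lists called 916 gained and 680 lost regions, so many of those were not called in the deposited lists. Shortening drops the weakest peaks, so a peak absent from a shortened list can be present in the deposited one.

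A second pattern was a slight departure of WX-02-43 from DMSO, for which a candidate explanation is that WX-02-43 partly opens the regions gained with WX-02-23. Regions were selected as held by the 3 WX-02-23 libraries and absent from a pair of reference libraries, with all 15 pairs of the other 6 as references in turn. In equal-length lists WX-02-43 libraries held 31.9% ± 0.46 of them and DMSO libraries 26.9% ± 2.2 (SD, n = 3 each), a difference of 5 points with a 90% interval from 2.24 to 7.48, with all 3 WX-02-43 libraries above all DMSO libraries (exact permutation p = 0.1, the smallest possible; chance gives such a separation in either direction in 10% of cases). In deposited lists the difference was 5.1 points with an interval from -23.32 to 27.67 (exact permutation p = 0.7), so the direction agreed but was within the spread. The same groups were also parted by a measure of the lists themselves: the median fold per list was 6.65 to 6.97 in WX-02-43 and 7.08 to 7.47 in DMSO (difference -0.47, 90% interval -0.82 to -0.11, exact permutation p = 0.1, adjusted p = 0.3), and background pileup averaged 1.34 ± 0.1 against 1.15 ± 0.07, so chance and a difference in library quality both remain open.

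The surroundings of the changed regions were also tested. Gained regions had a median of 16.5 regions held by all 9 libraries within 500 kb, against 20 for matched regions, but 16 of 84 splits differed by as much (highest other 9), and for lost regions, with 18 against 20, 51 of 84 did (highest other 8), and the small sets of the other splits (medians of 57 and 47 regions) leave this open as well. In equal-length lists 9.8% of gained regions had another within 100 kb, against a median of 7.6% in 10000 random matched sets (permutation p = 0.0415, adjusted p = 0.062), and 6.4% lay within 100 kb of a lost region, against 5% (permutation p = 0.0185, adjusted p = 0.055). Of lost regions, 5% had another lost region within 100 kb, against 5.3% (permutation p = 0.6305, adjusted p = 0.63). In deposited lists the corresponding values were 11.1%, 4.7% and 7.5% (adjusted p = 0.09, 0.09 and 0.016 by the same permutation test), so no clustering held in both settings after adjustment.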
